A study of Arabidopsis thaliana with 12 samples.

How the data were processed

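The deposited files were 9 comparison tables, each holding 4 libraries, so that each of the 12 libraries was in 3 tables, with 0 disagreeing values between them. Per the file headers, the authors gave counts for each library, a log2 fold change, and a p-value with a false discovery rate for each gene. The counts were whole numbers and were used as raw counts. The deposited log2 fold changes were read as log2 ratios and the deposited p-values and false discovery rates as the authors' own test results, and both were used only where the authors' deposited table is named. The 36 further library columns in the tables are pseudo-counts and were not used here. Per the submitters' processing notes, SAMtools, Picard, DESeq and edgeR were used on build TAIR10, with no versions or roles stated. The aligner is not given in the sources used here. Positions are from the TAIR10.1 annotation.

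The tables held 17777 to 18171 rows each and 18689 identifiers in all. Left out were 147 identifiers with a transcript suffix, of which 146 repeated the value of their gene, and 791 genes without counts in all 12 libraries, since each deposited table had already been filtered to genes with at least 1 CPM in at least 2 libraries. This left 17751 of 18542 genes. The edgeR filter (filterByExpr) removed 0 of them. Of counts from 1 to 20, 72.7% to 87.46% were even, so mates of a read pair were probably counted as 2 reads, and counting intervals are then too narrow. Whether counting was stranded is not given in the sources used here, so antisense transcripts may be included. Reads may be shared between paralogs (RBCS and LHCB1 genes, AT3G28290 and AT3G28300) and between overlapping genes (AT2G04378 and AT2G04380, AT4G19239 and AT4G19240).

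Counts were scaled by TMM and fitted with edgeR 4.0.16 quasi-likelihood in R 4.3.3, with 1 coefficient for each of the 6 groups. Contrasts gave the effect of salt in each genotype, the differences between genotypes within each condition, and the difference of each mutant's salt response from that of Col-0. The two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, and a gene was called at an adjusted p under 0.05. DESeq2 1.42.0 was the alternative. The 21 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of 231 list tests, camera called 85, and 0 held with an estimated correlation (lowest adjusted p = 0.0751). That setting was not part of the self-test below, and since it called 0 lists it cannot rank them. With fry, 181 list results were unchanged, 21 weaker and 29 stronger. The median, the mean and the direction of the test differed in sign in 38 list tests, of which 0 were called. Within each list, genes were also adjusted over the list alone, and for many called lists that count is given where it differs. These choices were made before the data were examined.

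Genes were named by rule. AGO4 was given everywhere. For each salt comparison and each comparison with Col-0, the rule took the 5 largest changes per direction past the threshold with a mean normalized count of at least 50 in the higher group, a finite fold change, and both libraries of one group above both of the other. A finite fold change was read as at least 1 count in the lower group. Up to 4 members of each list were taken by smallest adjusted p, with 5 genes per direction changed in both mutants and 5 per direction in each interaction. The text gives a selection of these, preferring calls that held with every library left out. Where a group had 1 to 3 counts in all, the ratio is given with its 95% counting interval, and against 0 counts the bound is that of 3 counts per library. Intervals and floors cover counting error only.

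The design text calls the libraries biological replicates, but nothing in it says that they came from separate cultures, so the p-values measure only the spread between these samples. With 1 library left out, its group is assumed to vary like the others. In a self-test on simulated counts shaped like the Col-0 salt comparison, edgeR recovered 83% of 100 genes changed 2-fold and 96% of 100 changed 4-fold, and called 11 of 17511 unchanged genes. DESeq2 recovered 84% and 96% and called 22. With no change simulated on the ago4-2 salt comparison, 1 gene was called. A planted list gave a camera p of 1.35e-36 and a fry p of 7.74e-06, and an unchanged list a camera p of 0.844. Genes were simulated independently of each other, whereas the storage list had an estimated correlation of 0.6473 for salt in Col-0. The self-test therefore cannot show how camera behaves on lists with correlated members.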

Results

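The series measured polyadenylated RNA of germinating Arabidopsis thaliana seeds by sequencing, to ask what the small RNA-binding protein AGO4 contributes to germination under salt. AGO4 guides DNA methylation to sequences matched by short RNAs. Wild type Col-0 and seeds of the mutant lines ago4-2 and ago4-3 were kept on MS 1X medium, as control, or on the same medium with 100 mM NaCl, at 21 °C with 16 h of light. Each of the 6 groups had 2 libraries of 18168653 to 47517007 counts. Values are log2 fold changes ± SE from edgeR quasi-likelihood fits of the deposited counts of 17751 genes, with Benjamini-Hochberg adjusted p, and group means ± SD of CPM, the counts scaled to library size (n = 2).

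AGO4 (AT2G27040; TAIR10.1 chromosome 2, 11536502 to 11542391) was nearly absent from ago4-3 and present at the wild-type level in ago4-2. In control, Col-0 held 45.7 ± 1.54 CPM, ago4-2 44.8 ± 6.13 and ago4-3 1.25 ± 0.136. In NaCl, the means were 42.9 ± 5.64, 37.1 ± 2.48 and 0.639 ± 0.127. The edgeR log2 fold change of ago4-3 against Col-0 was −5.17 ± 0.18 (adjusted p = 2.38e-10) in control and −6.09 ± 0.20 (adjusted p = 9.14e-11) in NaCl. For ago4-2 it was −0.02 (adjusted p = 0.930) and −0.21 (adjusted p = 0.229). Between the mutants, ago4-3 held less than ago4-2 in control (−5.15) and in NaCl (−5.88). A salt effect on the transcript was not called in Col-0 (−0.09, adjusted p = 0.687) or in ago4-2 (−0.28, adjusted p = 0.110). The small residue in ago4-3 was lower in NaCl (−1.01, adjusted p = 0.0198), a call that ended without ago4-3 control replicate 1 (adjusted p = 0.136) or without ago4-3 NaCl replicate 2 (adjusted p = 0.157). In ago4-2 the fall was called (adjusted p = 0.0347) without ago4-2 control replicate 1. Neither response to salt was called different from that of Col-0 (adjusted p = 0.661 for ago4-2 and 0.630 for ago4-3).

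**Figure D1:**
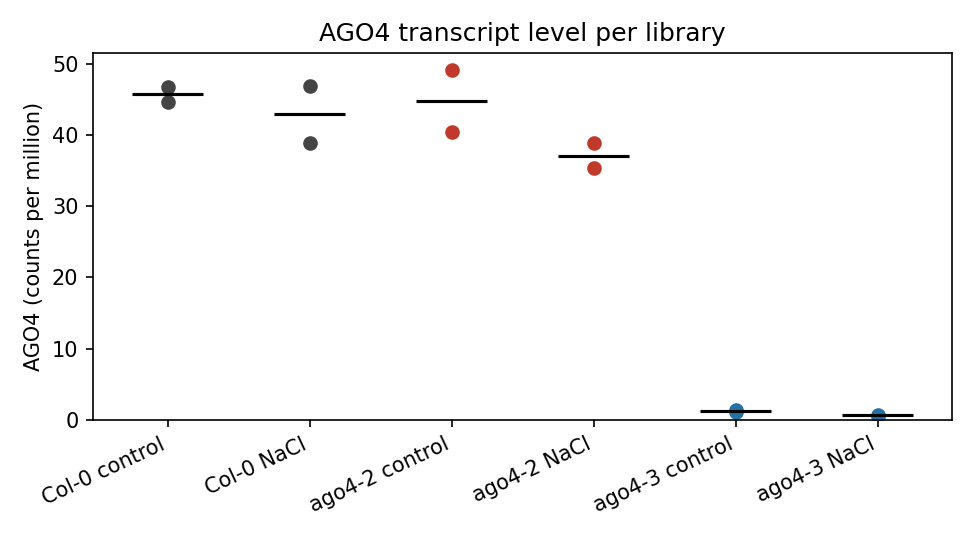
AGO4 level in CPM (vertical axis) in each of the 12 libraries, by genotype and condition, with points for libraries and a black line for the group mean. Both ago4-3 groups lie at or below 1.35 CPM, and every other library lies between 35.4 and 49.1 CPM.

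In Col-0, salt raised 34 of 42 photosynthesis genes and 18 of 24 LEA genes, which protect drying seeds, and lowered 5 of 10 heat shock genes. These list calls did not hold with an estimated correlation (camera adjusted p = 0.167, 0.285 and 0.167). Single genes of seed storage, the cell wall and the clock changed too. The largest rises were in the defensin PDF2.5 (4.82), the cysteine endopeptidase CEP2 (AT3G48340; 4.22 ± 0.23, adjusted p = 5.29e-08, from 1.84 to 34.6 ± 2.19 CPM), the defensin-like AT4G22217 (3.96), the extensin-like AT5G06630 (3.51) and AT5G44417 (3.46). The largest falls were in the clock factor LHY (AT1G01060; −4.13 ± 0.22, from 22.84 to 1.299 CPM), the lactone oxidase GulLO5 (−4.00), the cysteine proteinase AT1G29090 (−3.50), the xyloglucan hydrolase XTH24 (−3.45) and the peroxidase AT5G64100 (−3.34). The light-harvesting protein LHCB1.3 (AT1G29930) rose by 2.16 ± 0.11, from 33.7 ± 0.969 to 151 ± 5.78 CPM (adjusted p = 5.29e-08), with LHCB1.2 (2.19), the photosystem I subunit PSAD1 (2.13) and LHCA4 (2.03). The storage globulin CRA1 (AT5G44120) rose by 3.18 ± 0.22, from 67.2 ± 12.4 to 607 ± 167 CPM (adjusted p = 6.01e-07), beside the vicilin-like PAP85 (2.42) and the oil-body proteins OLEO2 (2.18) and OLEO5 (1.82). Of genes responsive to abscisic acid, which were not called as a list, those that rose included KIN1 (2.89), the annexin ANNAT1 (2.60), TSPO (1.54) and RD29A, and the LEA gene AT2G42560 rose as well. The germination repressor SOM (1.33) and the dormancy-related DOGL4 (1.52) rose. The abscisic acid synthesis gene ABA1 rose (1.02) and the catabolic gene CYP707A1 fell (−1.08), while the gibberellin synthesis gene GA3OX2 fell (−0.79) and GASA4 rose (0.84). Of the wall enzymes, XTH15 (−1.76), XTH9 (−1.52) and XTH16 (−1.37) fell, whereas the expansin EXPA10 rose (1.17). The root-hair genes PRP3 (2.95) and PRX73 (2.70) and the stomatal factor MUTE (1.87) rose, and the replication genes PCNA1 (−0.59) and MCM7 (−0.64) fell.

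In all, 1904 genes rose and 1318 fell in Col-0. The total of 3222 was 1618 without Col-0 control replicate 1, 1390 without Col-0 control replicate 2 and 2108 without Col-0 NaCl replicate 2. Among fixed lists, 34 of 42 photosynthesis genes rose and 0 fell, or 35 and 0 adjusted over the list alone (camera adjusted p = 1.25e-22, and adjusted p = 0.167 with an estimated correlation), as did 18 of 24 LEA genes with 0 falling, or 18 and 1 over the list alone (1.92e-10, and 0.285). Of 10 heat shock genes 5 fell (0.00319, and 0.167), and of 12 dormancy genes 4 rose (0.0339, and 0.199, ending at 0.123 without Col-0 NaCl replicate 1). Storage genes rose in 6 of 16 and fell in 1, osmotic stress genes rose in 10 of 21 and fell in 6, both at camera adjusted p = 0.0592. Without Col-0 control replicate 2 these became 0.00417 and 0.0264, and without Col-0 NaCl replicate 1 they became 0.00525 and 0.0158. Of 24 cell-wall loosening genes 5 rose and 8 fell (0.0761). The fixed list for silencing by DNA methylation had 2 measured genes, EPF2 and ROS1, and methylation promotes rather than silences ROS1. With ROS1 higher (0.0761), the list was called at 0.0445 without Col-0 control replicate 1 and at 0.0401 without Col-0 NaCl replicate 1. Also not called were the lists for methylation machinery (4 of 27 higher and 2 lower, 0.888), abscisic acid (6 of 39 and 9, 0.953), gibberellin (5 of 21 and 3, 0.937), cell cycle (3 of 24 and 8, 0.687), flavonoids (2 of 14 and 2, 0.888), lipid mobilisation (2 of 16 and 0, 0.937), defence (1 of 6 and 1, 0.937), root (3 of 7 and 1, 0.714), shoot epidermis (2 of 7 and 2, 0.714), and endosperm and seed coat (0 of 4 and 1, 0.714). No member was called in the lists for ion transport (9 genes, 0.937), organelles (119 genes, 0.888) and transposable elements (21 genes, 0.639). In the authors' deposited table, 2216 genes were higher and 1886 lower, of which 2853 were called in the same direction in the refit.

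In ago4-2, salt raised 20 of 24 LEA and 10 of 16 seed storage genes and lowered 14 of 24 cell-wall loosening genes, and 2 of 42 photosynthesis genes rose, against 34 in Col-0. The first 3 list calls did not hold with an estimated correlation (camera adjusted p = 0.399, 0.722 and 0.399). The largest rises were in CEP2 (4.91), the linker histone HIS1-3 (AT2G18050; 4.14, from 2.41 to 41.9 CPM), the RING protein AT2G27940 (3.97), PAP85 (3.95) and the uncharacterized AT1G68250 (3.88). The largest falls were in AT5G09570, a Cox19-like CHCH protein (−5.67 ± 0.32), the stress zinc-finger protein PMZ (−4.79), the clock factor CCA1 (−3.98), AT1G29090 (−3.93) and XTH17, which was 79.1-fold lower (95% counting interval 21.5 to 660). CRA1 rose by 3.28, from 625 ± 3.22 to 6070 ± 397 CPM, with OLEO2 at 3.01 and OLEO5 at 2.57. AT2G42560 (3.44), RD29A (3.12), TSPO (2.73), EM1 (2.55), RD29B (2.49) and DREB2A (1.55) rose. The chlorophyll synthesis gene CHLH fell (−2.35), as did the photosystem II gene PSBO1 (−1.97), RBCS3B (−1.38) and RCA (−1.26). The abscisic acid phosphatases HAI3 (2.14) and AHG1 (1.90) rose while the receptors PYL6 (−1.86) and PYL2 (−1.34) fell. GASA6 (−2.45), GA3OX2 (−2.02), the expansin EXPA8 (−2.25), XTH18 (−3.35) and the flavonoid genes UF3GT (−4.33), LDOX (−1.57) and TT5 (−1.07) also fell, as did HSP17.4 (−1.51) and HSP101 (−1.14). SOM (1.66) and DOGL4 (2.57) rose.

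Salt changed 6238 genes in ago4-2, 3085 upward and 3153 downward, and 3916 without ago4-2 NaCl replicate 2. Of the fixed lists, storage genes rose in 10 of 16 and fell in 2, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.0195, and 0.722 with an estimated correlation). LEA genes rose in 20 of 24 and fell in 4 (4.4e-10, and 0.399), and cell-wall loosening genes rose in 4 and fell in 14 of 24 (0.00165, and 0.399). Dormancy genes rose in 6 of 12 and fell in 1 (0.0214, and 0.399). Photosynthesis genes rose in 2 of 42 and fell in 16, or 4 and 16 over the list alone (0.0141, and 0.722). That call ended without ago4-2 NaCl replicate 1 (0.0875), as did those of the flavonoid list (2 of 14 higher and 9 lower, 0.0275, and 0.718, to 0.0875) and of the heat shock list (6 of 10 lower, 0.0279, and 0.399, to 0.0612). Without ago4-2 control replicate 1 the heat shock list and the osmotic stress list (9 of 21 higher and 5 lower, 0.0291, and 0.399) both moved to 0.067, and without ago4-2 control replicate 2 the flavonoid list moved to 0.0589. The other 13 lists were not called. Of these, the root list moved from 0.105 to 0.036 without ago4-2 NaCl replicate 2, and the DNA methylation machinery from 0.086 to 0.0281 without ago4-2 control replicate 2. The organelle list (0.086) moved to 1.03e-15 without ago4-2 control replicate 1 and to 0.0454 without ago4-2 NaCl replicate 2, and lay in the other direction without ago4-2 control replicate 2 (5.35e-05). The authors' deposited table had 2134 genes higher and 2018 lower, with 3765 shared in direction.

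In ago4-3, salt raised 19 of 24 LEA genes, raised 27 and lowered 6 of 42 photosynthesis genes, and lowered 7 of 10 heat shock genes. These list calls did not hold with an estimated correlation (camera adjusted p = 0.232, 0.498 and 0.232). The largest rises were in the dynein light chain AT3G16120 (4.83), the defensin-like AT4G22217 (4.51), the dehydrin AT5G66400 (4.37, from 31.8 ± 17.7 to 664 ± 8.84 CPM), the dormancy-associated AT2G33830 (4.35) and the methyltransferase HMT3, at 52.3-fold (95% counting interval 14.1 to 437). The largest falls were in AT5G09570 (−4.65), LHY (−4.53), the glutathione transferase GSTF7 (−4.40), the peroxidase AT5G39580, 41.4-fold lower (13.8 to 203), and the mitochondrial ATMG00990, 43.1-fold lower (11.6 to 362). CRA1 rose by 3.82, from 87.2 ± 22.4 to 1234 ± 64.5 CPM, with KIN1 (3.68), DOGL4 (3.15), EM1 (2.74), OLEO5 (2.56) and RD29B (2.29). LHCA4 (1.61), PSAD1 (1.52) and LHCB1.3 rose. AHG1 (1.81), SOM (1.52), GA20OX3 (1.49) and the flavonoid gene TT7 (1.22) rose, and XTH18 (−4.14), XTH22 (−2.20), CYP707A3 (−1.78) and HSP17.4 (−1.70) fell.

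Here 2242 genes rose and 1847 fell. The total of 4089 was 2521 without ago4-3 control replicate 2 and 2128 without ago4-3 NaCl replicate 1. LEA genes rose in 19 of 24 and fell in 0, or rose in 20 and fell in 1 when adjusted over the list alone (camera adjusted p = 1.85e-14, and 0.232 with an estimated correlation). Photosynthesis genes rose in 27 of 42 and fell in 6, or 28 and 6 over the list alone (1.56e-06, and 0.498), and heat shock genes fell in 7 of 10 (0.0129, and 0.232). Organelle genes fell in 24 of 119, but in 1 over the list alone, with a median of −1.99 (2.76e-11, and 0.774). Their share of counts was 0.102% (95% Wilson interval 0.1 to 0.103) in ago4-3 NaCl replicate 1 and 0.585% (0.582 to 0.587) in replicate 2. Storage genes rose in 7 of 16 and fell in 1, or 8 and 3 over the list alone (0.0129, and 0.774), which ended at 0.431 without ago4-3 control replicate 2. The dormancy list (5 of 12 higher, or 5 higher and 1 lower over the list alone, 0.0275, and 0.232) and the cell cycle list (9 of 24 lower, or 9 lower and 1 higher over the list alone, 0.0332, and 0.498) both ended at 0.0721 without ago4-3 control replicate 1, and at 0.0548 and 0.113 without ago4-3 NaCl replicate 1. The osmotic stress list (9 of 21 higher and 6 lower, 0.0829) was called at 0.041 without ago4-3 NaCl replicate 2. The other 13 lists were not called. Across the 3 genotypes, 1114 genes rose and 848 fell in each. Col-0 shared 1246 rises and 1032 falls with ago4-2, against 330.9 and 234.1 for independent sets, and 1404 and 988 with ago4-3, against 240.5 and 137.1. The authors' deposited table had 2081 genes higher and 1960 lower, with 3180 shared in direction.

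**Figure D2:**
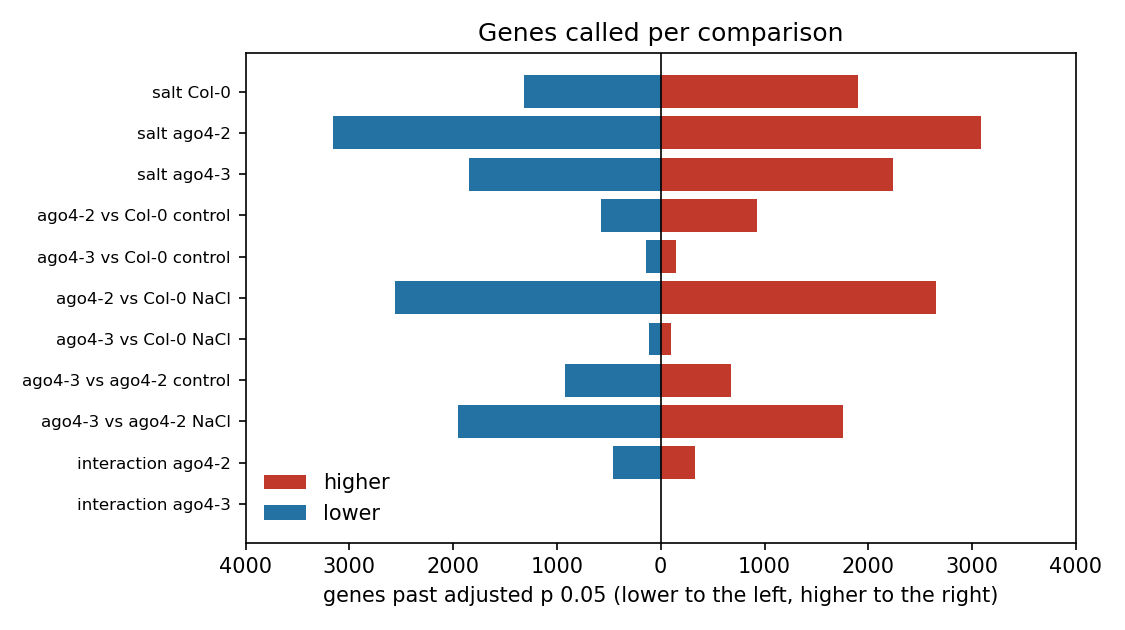
Number of genes past an adjusted p of 0.05 (edgeR, Benjamini-Hochberg) in each comparison, with bars to one side for higher and to the other for lower genes. Salt in ago4-2 has the longest bars, 3085 higher and 3153 lower, and the ago4-3 interaction the shortest, 2 and 2.

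In control, ago4-2 held more of all 16 seed storage transcripts than Col-0, and genes that were close to silent in one line and expressed in the other. CRA1 stood at 625 ± 3.22 CPM in ago4-2 and 67.2 ± 12.4 in Col-0 (3.22), the cruciferin CRC (AT4G28520) at 660 and 42.2 CPM (3.97), and the albumins SESA2 (3.99) and SESA1 (3.01) were also higher. The glucosinolate-hydrolysis gene ESM1 (AT3G14210; chromosome 3, 4729399 to 4731847) stood at 60.8 ± 14.5 CPM against 0.498 in Col-0 (6.91 ± 0.22), and the dirigent-like AT2G21100 at 28.1 against 0.158 (7.33). AT4G32230 was 414-fold higher (95% counting interval 114 to 3430), the noncoding AT4G04077 230-fold (63 to 1910) and AT4G10201 195-fold (34.3 to 7770). The retroposon SADHU1-1 (AT2G10410) was lower, at 0.200 against 128 ± 15.8 CPM (−9.14), with AT2G04378 (−8.71), the overlapping AT2G04380 (−8.40), the noncoding AT2G09795 (408-fold, 140 to 1980) and the DNA-binding protein gene AT3G47680 (294-fold, 81.1 to 2430). Of 24 LEA genes 16 were higher, among them M17 by 2.02, EM6 by 1.73 and AT2G42560 by 1.34. That list call did not hold with an estimated correlation (camera adjusted p = 0.411). Cold and osmotic genes split, with KIN2 (−2.17), RD29A (−1.63) and LTP3 (−1.37) lower and TSPO higher (1.31). The methylation genes SUVH9 (−1.14), CMT3 (−0.91) and MET1 (−0.75) and the flavonoid regulator MYB12 (−1.52) were lower. The resistance gene RPP4 (3.86), the stomatal genes MUTE (2.75) and EPF1 (2.18), LDOX (2.15), PSAD1 (0.94), EXPA15 (0.88) and SOM (0.73) were higher, and CYP707A1 was lower (−1.18). SUVH9 (start 7823894), RPP4 (9488466) and CYP707A1 (10521259) lie on chromosome 4 among genes close to silent in one line (AT4G12870, 7542233, to AT4G19239, 10527516). For them, linked background and an effect of ago4-2 cannot be told apart. The same limit holds for LDOX (12004726), SESA1 (13607329), SESA2 (13609341) and CRC (14087556). They lie between AT4G19239 and AT4G32230 (15565295), a stretch of chromosome 4 with further such genes.

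There were 927 genes higher and 571 lower. This total of 1498 was 533 without Col-0 control replicate 1, 563 without Col-0 control replicate 2, 782 without ago4-2 control replicate 1 and 2420 without ago4-2 control replicate 2, and 887 fitted on its own groups. The pair of ago4-2 control libraries spread most, with a coefficient of variation of 18.78%, and organelle genes took 2.04% (95% Wilson interval 2.03 to 2.05) of counts in replicate 1 and 0.202% (0.2 to 0.203) in replicate 2. All 16 storage genes were higher, with a median of 3.12 (camera adjusted p = 1.03e-18, and 0.411 with an estimated correlation), as were 16 of 24 LEA genes with 0 lower, or 17 and 3 adjusted over the list alone (1.05e-07, and 0.411), and 2 of 7 shoot epidermis genes, or 3 over the list alone (0.00494, and 0.411). Organelle genes were higher in 6 of 119, or 43 over the list alone (1.58e-05, and 0.814), but without ago4-2 control replicate 1 the list lay in the other direction (0.00638). The cell cycle list, with 1 of 24 lower (0.0145, and 0.411), ended at 0.0693 without the same library. The other 16 lists were not called, and 1 of 21 transposable element genes, SADHU1-1, was lower (0.0645). Without Col-0 control replicate 2 the transposable element list (0.0352) and the gibberellin list (8 of 21 higher and 1 lower, 0.0516, to 0.0315) were called. The osmotic stress list had 4 of 21 higher and 7 lower (0.675), with a median of 0.17 and a mean of −0.16. In the authors' deposited table, 756 genes were higher and 669 lower, with 930 shared in direction.

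In control, ago4-3 differed from Col-0 in 294 genes, or 624 fitted on its own groups and 465 with DESeq2, and 0 of 16 storage genes were among the 294. ESM1 was higher by 9.68 ± 0.23 (412 ± 41.7 against 0.498 CPM, adjusted p = 1.58e-12), with AT4G08093 (7.04), AT5G35935 (6.54), AT2G21100 (6.21) and the noncoding AT2G01422 (5.39). After AGO4, the lowest were the cysteine protease AT1G29080 (−3.59), the TRAF-like AT3G28220 (−3.56), AT4G08115 (−3.47) and the thioredoxin peroxidase AT1G65970 (−3.40). The DNA demethylase gene ROS1 (AT2G36490) stood at 1.39 against 5.11 CPM (−1.88 ± 0.22, adjusted p = 2.44e-04). ICS1, which makes salicylic acid, stood at 29.6 ± 1.58 against 7.55 CPM (1.97, adjusted p = 7.86e-06). The anthocyanin genes DFR (3.37) and LDOX (3.10) were higher, as was LHCB1.3 (0.76). Lower genes included DOGL4 (−2.73), M17 (−2.57), the endosperm expansin EXPA2 (−2.19), HAI3 (−1.75), GASA6 (−1.54), LTP3 (−1.45), the dormancy gene RDO5 (−1.21) and RD29A (−1.07). The calls of AT4G08115 and AT3G28220 ended without Col-0 control replicate 1, at adjusted p = 0.0763 and 0.0691.

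Of 294 genes, 151 were higher and 143 lower, and the total was 98 without Col-0 control replicate 1, 92 without Col-0 control replicate 2 and 99 without ago4-3 control replicate 2. Photosynthesis genes were higher in 6 of 42, or 20 adjusted over the list alone (camera adjusted p = 4.82e-14, and 0.169 with an estimated correlation). Flavonoid genes were higher in 5 of 14, or 8 over the list alone (2.81e-09, and 0.114), and cell cycle genes in 3 of 24, or 11 over the list alone (1.01e-09, and 0.114). LEA genes were lower in 3 of 24, or 6 over the list alone (1.65e-06, and 0.28), heat shock genes in 4 of 10, or 6 over the list alone (0.00254, and 0.114) and osmotic stress genes in 3 of 21 (0.00398, and 0.169). Organelle genes were higher in 1 of 119, or 70 over the list alone, with a positive median (6.27e-22, and 0.333). Their share of counts varied within groups, at 0.44% and 0.198% in the Col-0 control libraries and 1.4% and 0.933% in those of ago4-3. Whether library preparation or genotype set this share was not tested. The endosperm and seed coat list (1 of 4 lower, or 2 over the list alone, 0.00164, and 0.114), the root list (1 of 7 higher, or 2 over the list alone, 0.0133, and 0.285) and the ion transport list (0 of 9 called, or 1 lower over the list alone, 0.0154, and 0.205) were also called. Storage genes had 0 of 16 called, or 3 over the list alone (0.0799), and were called at 0.000822 without Col-0 control replicate 2 and 7.45e-11 without ago4-3 control replicate 2. Without ago4-3 control replicate 2 the lists of EPF2 and ROS1 (0.0548, to 0.0311), gibberellin (0.217, to 0.00462), dormancy (0.0859, to 0.0368) and cell-wall loosening (0.21, to 0.0191) were called too. EPF2 and ROS1 were also called without Col-0 control replicate 2 (0.00695). The authors' deposited table had 702 genes higher and 824 lower, with 288 shared in direction.

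In NaCl, ago4-2 held more of all 16 storage and of 20 of 24 LEA transcripts (3 lower) than Col-0, and less of 39 of 42 photosynthesis transcripts. These list calls did not hold with an estimated correlation (camera adjusted p = 0.336, 0.336 and 0.256). CRC stood at 2589 ± 311 against 61.9 ± 31.6 CPM (5.39) and CRA1 at 6070 ± 397 against 607 ± 167 (3.32), with SESA2 (3.77), M17 (3.59), EM6 (3.07), OLEO2 (2.50) and AT2G42560 (2.48). The photosystem II antenna gene LHCB5 (AT4G10340) stood at 5.48 ± 1.26 against 41.9 ± 6.18 CPM (−2.92, adjusted p = 2.56e-08), beside PSBO1 (−2.29), LHCA4 (−1.70) and CHLH, at −2.54. LHCB5 (chromosome 4, start 6408007) lies close to AT4G10220 (6362189), which was near silent in Col-0 only. Linked background cannot be told apart for it. The same holds for CRC, SESA2 and XTH19, between AT4G24420 (12626640) and AT4G32230 (15565295) on chromosome 4, and for LHCA4. LHCA4 (chromosome 3, start 17493343) lies close to AT3G47680 (17577398), which was near silent in ago4-2 but not in Col-0. The largest differences upward were AT2G21100 (9.18), AT4G04077 (8.52, at 22.8 against 0.0577 CPM), the AT14A-family gene AT3G28300 (7.35), the resistance-type gene AT4G11170 (256-fold, 95% counting interval 87 to 1240) and the cystine lyase CORI3 (238-fold, 65.3 to 1970). ESM1 was higher by 6.80. The largest downward were SADHU1-1 (−9.91), AT2G04378 (1730-fold, 479 to 14300), AT4G10690 (1410-fold, 253 to 55800), AT2G04380 (1400-fold, 387 to 11500) and AT3G47680 (389-fold, 107 to 3220). AHG1 (2.02), the abscisic acid factor ABI5 (0.82), TSPO (2.50), SOM (1.06), the flowering repressor FLC (1.01), the DELLA gene GAI (0.70), RPP4 (4.41), HSP70 (0.68), MAN7 (0.77), ACX1 (0.69) and IDN2 (0.49) were higher. KIN2 (−1.58), EXPA8 (−1.69), FLS1 (−1.15), EXPA1 (−0.93), XTH19 (−0.89), SUVH9 (−0.85), PYL2 (−0.84), TT4 (−0.76), GA3OX2 (−0.74) and SPT (−0.66) were lower.

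Here 2649 genes were higher and 2560 lower. The total of 5209 was 3439 without Col-0 NaCl replicate 1, 3009 without ago4-2 NaCl replicate 1 and 2804 without ago4-2 NaCl replicate 2. All 16 storage genes were higher, with a median of 3.55 (camera adjusted p = 2.12e-14, and 0.336 with an estimated correlation), and LEA genes were higher in 20 of 24 and lower in 3 (2.38e-10, and 0.336). Photosynthesis genes were lower in 39 of 42, or 40 adjusted over the list alone, with a median of −1.32 (1.2e-25, and 0.256). Organelle genes were higher in 13 of 119, but in 3 over the list alone (5e-07, and 0.666). The flavonoid list (1 of 14 higher and 6 lower, or 1 and 7 over the list alone, 0.0396, and 0.603) ended at 0.0771 without Col-0 NaCl replicate 2 and at 0.21 without ago4-2 NaCl replicate 1. The cell cycle list (5 of 24 lower, 0.0458, and 0.566) ended at 0.206, 0.0863 and 0.0644 without Col-0 NaCl replicate 1, ago4-2 NaCl replicate 1 and ago4-2 NaCl replicate 2. The other 15 lists were not called, and the list of EPF2 and ROS1 (0.0634) was called at 0.0344 without Col-0 NaCl replicate 1. The 6 defence genes had 1 higher and 4 lower (0.368), with a median of −0.81 and a mean of 0.13. In the authors' deposited table, 2932 genes were higher and 3303 lower, with 4728 shared in direction.

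In NaCl, ago4-3 differed from Col-0 in 211 genes, or 348 with DESeq2, with the demethylase gene ROS1 lower and ESM1, ICS1 and the anthocyanin gene LDOX higher. ESM1 stood at 757 ± 22.2 against 0.894 CPM (9.72), with AT3G28300 (9.14) and AT3G28290 (8.79), paralogs whose reads may be shared, the MADS-box gene AT1G59930 (396-fold, 95% counting interval 109 to 3280) and AT2G11410 (743-fold, 205 to 6140). ICS1 stood at 26.2 against 5.61 CPM (2.22, adjusted p = 1.90e-06) and LDOX was higher (2.35). After AGO4 the lowest were GSTF7 (−4.74), AT1G65970 (−4.67), the polyketide cyclase-like AT1G14950 (−4.28) and AT5G09570 (−3.92). ROS1 stood at 0.766 against 8.21 CPM (−3.42 ± 0.24, adjusted p = 6.98e-07). AT2G27380 (−2.33), HSP17.4 (1.574 against 6.75 CPM) and EXPA2 (−1.70) were lower. The call of GSTF7 ended without Col-0 NaCl replicate 1 (adjusted p = 0.061), ago4-3 NaCl replicate 1 (0.0954) or ago4-3 NaCl replicate 2 (0.137).

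There were 96 genes higher and 115 lower, and the total of 211 was 104 without Col-0 NaCl replicate 1, 87 without ago4-3 NaCl replicate 1 and 105 without ago4-3 NaCl replicate 2. Flavonoid genes were higher in 4 of 14, or 7 adjusted over the list alone (camera adjusted p = 1.02e-06, and 0.215 with an estimated correlation). Storage genes were higher in 3 of 16, or 6 over the list alone (2.36e-06, and 0.463), and LEA genes in 2 of 24 with 1 lower, or 11 and 1 over the list alone (0.000146, and 0.463). The list of EPF2 and ROS1 was called (0.000102, and 0.105) with 1 of its 2 genes, ROS1, lower. Without Col-0 NaCl replicate 2 the calls of photosynthesis (0 of 42 called, or 1 lower over the list alone, 0.000102, and 0.463, to 0.0855), cell cycle (0 of 24, 0.00056, and 0.237, to 0.136), heat shock (3 of 10 lower, or 4 lower and 1 higher over the list alone, 0.00835, and 0.215, to 0.0666) and endosperm and seed coat (2 of 4 lower, 0.00835, and 0.216, to 0.119) ended, and photosynthesis also ended at 0.0907 without ago4-3 NaCl replicate 2. The other 13 lists were not called. Of these, the root list (0.0517) was called at 0.00561 and the organelle list (0.207) at 7.5e-05 without Col-0 NaCl replicate 1, as were gibberellin (0.316, to 0.0114) and osmotic stress (0.372, to 0.0143). The methylation machinery (0.207) was called at 0.00831 without Col-0 NaCl replicate 2, and cell-wall loosening (0.207) at 0.0413 without ago4-3 NaCl replicate 2. The authors' deposited table had 163 genes higher and 385 lower, with 189 shared in direction.

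Genes that moved the same way in both mutants included ESM1, AT2G21100 and the AT14A-family pair. The level in ago4-2 ran from 13.2% (ESM1 in NaCl) to 271% (AT2G21100 in NaCl) of that in ago4-3 over ESM1 and the 5 genes near on in both. In control, AT2G11410 was at least 43.1-fold higher in ago4-2 and at least 229-fold in ago4-3, AT3G28290 at least 26.4-fold and 60.4-fold, and AT4G01975 at least 25.3-fold and 34.1-fold. In NaCl, ESM1 was higher by 6.80 in ago4-2 and 9.72 in ago4-3, AT2G21100 by 9.18 and 7.73, and AT3G28290 by 6.78 and 8.79. Lower in both were AT5G09570 (−5.47 and −3.92), AT1G65970 (−2.58 and −4.67) and AT1G14950 (−2.31 and −4.28). In control, 52 genes were higher and 29 lower in both, against 7.886 and 4.6 for independent sets, with 20 in opposite directions. In NaCl, 56 were higher and 74 lower, against 14.33 and 16.58, with 11 opposite. Both mutants were compared with the same Col-0 libraries, and 20 simulations with no genotype effect gave a correlation of 0.475 in control and 0.487 in NaCl, against 0.3715 and 0.3747 observed, with covariances of 0.02342 and 0.02361 against 0.1094 and 0.1251. Part of the excess may come from the shared controls. The simulated sets shared a mean of 0.25 higher and 0 lower genes in control. With no change simulated, few genes can be called at all, so this does not bound the part due to shared controls. The control total of 81 was 22 without Col-0 control replicate 1, 24 without Col-0 control replicate 2, 37 without ago4-3 control replicate 2 and 223 without ago4-2 control replicate 2. The NaCl total of 130 was 59 without Col-0 NaCl replicate 1, 46 without ago4-3 NaCl replicate 1 and 59 without ago4-3 NaCl replicate 2.

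**Figure D3:**
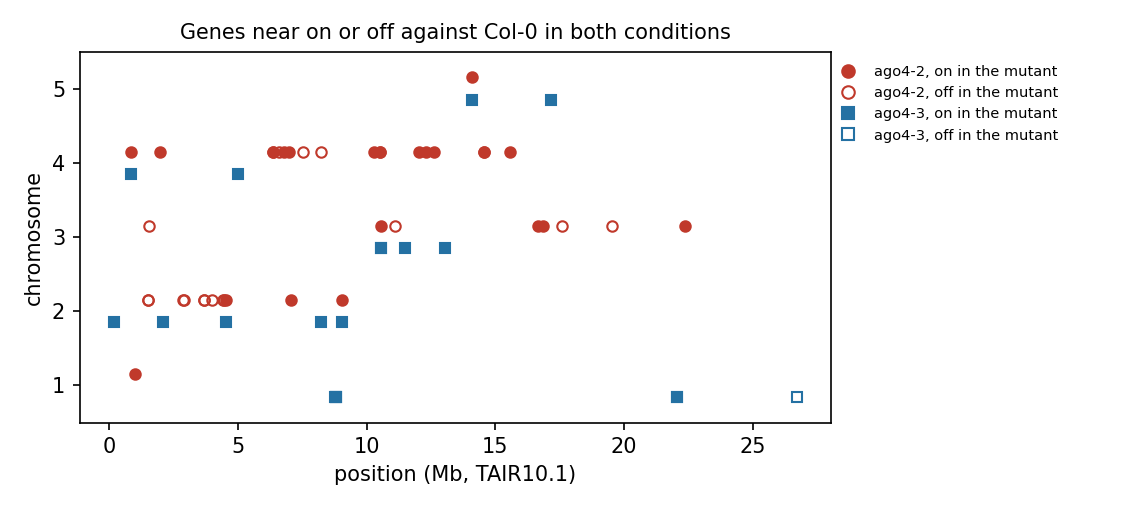
Position in Mb (TAIR10.1) along each chromosome of genes near on or off against Col-0 in both conditions, by limits of 0.5 and 2 CPM chosen after the values were seen, with circles for ago4-2, squares for ago4-3, filled symbols for on and open ones for off. Of 40 genes in ago4-2, 12, 8 and 18 lie on chromosomes 2, 3 and 4, and ago4-3 has 20.

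Set directly against each other, ago4-3 held less than ago4-2 of 15 of 16 storage genes and 19 of 24 LEA genes in each condition, and more of 38 of 42 photosynthesis genes in NaCl. With an estimated correlation these list calls did not hold (camera adjusted p from 0.111 to 0.173). In control, ago4-3 held less CRC (−3.40), SESA2 (−3.22), CRA1 (−2.84), M17 (−4.60), EM6 (−1.99), RPP4 (−4.75), EXPA2 (−2.89) and GASA6 (−2.31), and more SADHU1-1 (9.18), ICS1 (2.61), MYB12 (2.19), SUVH9 (1.42), LHCB5 (1.29), CMT3 (0.95) and MCM5 (0.72). In NaCl it held less RPP4 (−5.59), CRC (−4.03), M17 (−3.22), ROS1 (−2.80), CRA1, TSPO and AHG1 (−1.67), and more SADHU1-1 (10.18), ICS1 (3.09), LHCB5 (2.42), CHLH (2.42), LDOX (2.34), LHCB1.3 (1.42), EXPA8 (1.01) and GA3OX2 (1.00). In control, 673 genes were higher and 924 lower, a total of 1597 that was 879 without ago4-3 control replicate 2 and 650 fitted on its own groups. In NaCl, 1756 were higher and 1953 lower, and the total of 3709 was 1923 without ago4-2 NaCl replicate 1, 1867 without ago4-2 NaCl replicate 2, 2199 without ago4-3 NaCl replicate 1 and 2286 without ago4-3 NaCl replicate 2. Storage genes were lower in 15 of 16 in control (camera adjusted p = 1.56e-16, and 0.127 with an estimated correlation) and in 15 in NaCl, or 16 adjusted over the list alone (1.8e-13, and 0.159). Photosynthesis genes were higher in 10 of 42 in control, or 17 with 2 lower over the list alone (6.29e-05, and 0.268), and 38 in NaCl, or 40 over the list alone (1.9e-27, and 0.111). LEA genes were lower in 19 of 24 in both, or 20 and 21 over the list alone, at 4.71e-14 (0.127) and 1.4e-09 (0.173). Cell cycle genes were higher in 10 of 24 in control, or 21 over the list alone (1.23e-12, and 0.0771), and in 8 in NaCl, or 11 over the list alone (9.99e-06, and 0.111). Flavonoid genes were higher in 8 of 14 in control, or 10 over the list alone (1.13e-05, and 0.151) and 11 in NaCl (2.43e-08, and 0.111). Endosperm and seed coat genes were lower in 2 of 4 in control, or 3 over the list alone (median −1.45, 0.000747, and 0.127), and in 3 in NaCl, or 3 lower and 1 higher over the list alone (median −1.33, 0.0158, and 0.164). Heat shock genes were lower in 5 of 10 in control, or 7 over the list alone (0.00153, and 0.127), and 3 in NaCl, or 4 over the list alone (0.00603, and 0.111). In control the shoot epidermis list (3 of 7 lower, 0.00242, and 0.181) and the root list (1 of 7 higher, or 2 over the list alone, 0.017, and 0.26) were also called. The dormancy list was called in control (3 of 12 lower, or 6 lower and 1 higher over the list alone, 0.0153, and 0.127) and in NaCl (5 lower and 1 higher, or 6 and 1 over the list alone, 0.00972, and 0.111), the latter ending at 0.0601 without ago4-3 NaCl replicate 2. The control calls of EPF2 and ROS1 (0.034, and 0.163) ended at 0.0764 without ago4-2 control replicate 2, and those of gibberellin (0.00242, and 0.245) and defence (0.0201, and 0.225) at 0.0503 without ago4-3 control replicate 1. The organelle list was called upward in control (0.000523, and 0.639), with the other direction without ago4-2 control replicate 2 (3.73e-05), and downward in NaCl, with 8 of 119 lower, but 1 over the list alone (5.49e-10, and 0.584). The authors' deposited tables had 478 genes higher and 575 lower in control, with 842 shared in direction, and 2342 and 2690 in NaCl, with 3470 shared.

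The response to salt lay lower in ago4-2 than in Col-0 in 38 of 42 photosynthesis genes and higher in 11 of 24 LEA genes. These list calls did not hold with an estimated correlation (camera adjusted p = 0.0751 and 0.385). The interaction term of PSAD1 was −2.62 (edgeR adjusted p = 4.86e-06), with the plastocyanin PETE2 (−1.98), LHCB1.3 (−1.96) and PSBP1 (−1.62). The mean of PSAD1 went from 16.2 to 71 CPM in Col-0 but from 30.9 to 22 in ago4-2. PETE2 went from 73.7 to 123.8 CPM in Col-0 but from 102 to 43.1 in ago4-2, and PSBP1 likewise rose and fell. LHCB1.3 went from 33.7 to 151 CPM in Col-0 and from 49.7 to 57.2 in ago4-2. The clock gene GI (AT1G22770) differed by −3.19 ± 0.22 (adjusted p = 2.93e-06), AT5G09570 by −4.59 and the Rossmann-fold protein AT2G17845 by −3.30. EXPA8 (−2.07), EXPA1 (−1.32), EXPA10 (−1.29), GASA6 (−1.61), GA3OX2 (−1.23) and PYL2 (−1.26) lay lower in the ago4-2 response, and RD29A (1.62), AHG1 (1.33), the LEA gene AT1G72100 (1.25), RD29B (1.23) and TSPO lay higher. The term was positive in 326 genes and negative in 460, and the total of 786 was 298 without Col-0 control replicate 1, 254 without Col-0 control replicate 2, 319 without ago4-2 NaCl replicate 1 and 290 without ago4-2 NaCl replicate 2. Photosynthesis genes lay lower in 38 of 42, or 40 adjusted over the list alone, with a median of −1.45 (camera adjusted p = 1.87e-43, and 0.0751 with an estimated correlation). LEA genes lay higher in 11 of 24, or 13 with 2 lower over the list alone (2.66e-06, and 0.385). For ago4-3 the term was called in 2 genes upward and 2 downward. With 981 genes at unadjusted p under 0.05, edgeR quasi-likelihood called these 4, or 9 fitted on its own groups, and DESeq2 called 54. AT5G09570 (−3.56, adjusted p = 5.16e-04) held with every library left out. ILA, a translation regulator (1.33, adjusted p = 0.0104), M17 (2.94, adjusted p = 0.0104) and the Nudix hydrolase NUDT21 (−1.51, adjusted p = 0.0395) ended without Col-0 control replicate 1, at 0.0815, 0.0804 and 0.202. The 4 genes became 1 without Col-0 control replicate 1, Col-0 control replicate 2 or ago4-3 NaCl replicate 1, 12 without Col-0 NaCl replicate 2 and 19 without ago4-3 control replicate 1. Photosynthesis genes had 0 of 42 called for ago4-3, or 27 over the list alone (3.97e-26, and 0.123). Their median of −0.57 lay in the same direction as in ago4-2. The LEA median was 0.66 for ago4-3 and 0.68 for ago4-2.

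**Figure D4:**
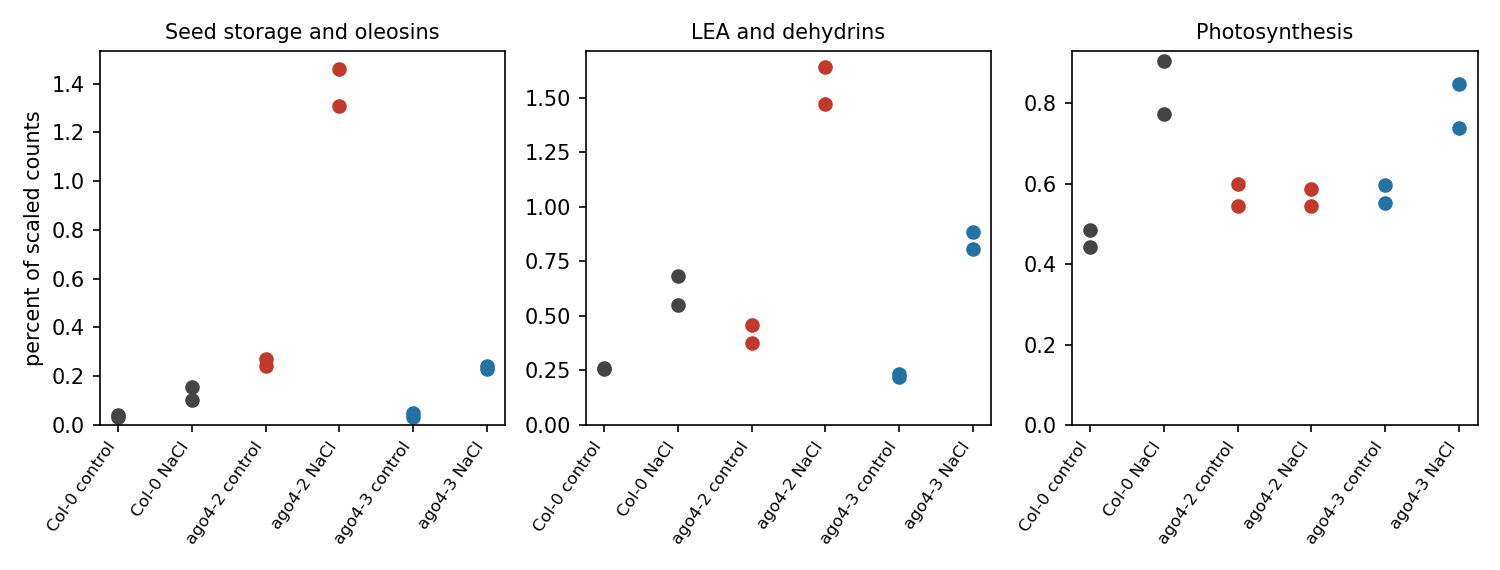
Percent of scaled counts (vertical axis) taken by the storage, LEA and photosynthesis lists in each of the 12 libraries, by genotype and condition, with a point per library. The storage share is highest in ago4-2 in NaCl, where CRA1 reached 6070 CPM against 607 CPM in Col-0.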

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

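Of the tests used here, the count of pairs of nearby genes, the share of on or off genes common to both mutants, the count of genes against mixing, the photosynthesis median in control and both clock tests were chosen after seeing the result. The test without the most abundant genes was written beforehand.

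The salt response differed between ago4-2 and Col-0, by the interaction term, in 786 genes. The lowest terms were those of AT5G09570 (−4.59), XTH17 (−4.25), PMZ (−3.35), AT2G17845 (−3.30) and GI (−3.19), and the highest those of AT1G31040 (2.22), the phloem protein gene SEOa (2.07), CBSX5 (2.05), the LEA gene ECP31 (1.97) and AT3G05260 (1.94). The calls of XTH17, PMZ, AT1G31040, SEOa, AT3G05260, ECP31 and CBSX5 all ended without Col-0 control replicate 2 (edgeR adjusted p from 0.0524 to 0.145). Camera called lists with medians of −1.45 for photosynthesis (38 of 42 genes lower), −0.91 for EPF2 and ROS1 (1 of 2 lower), −0.80 for shoot epidermis (3 of 7 lower), −0.56 for flavonoid (2 of 14 lower), −0.16 for cell-wall loosening (5 of 24 lower and 1 higher), 0.20 for osmotic stress (5 of 21 higher), 0.61 for storage (1 of 16 higher) and 0.68 for LEA genes (11 of 24 higher). With an estimated correlation none held, at adjusted p = 0.0751, 0.319, 0.385, 0.385, 0.58, 0.385, 0.745 and 0.385 in that order. For ago4-3 the term differed in 4 genes, AT5G09570 (−3.56), NUDT21 (−1.51), ILA (1.33) and M17 (2.94). Lists called for ago4-3 had medians of −2.24 for organelle, −1.06 for EPF2 and ROS1, −0.57 for photosynthesis, −0.18 for cell cycle, 0.30 for storage and 0.66 for LEA genes. Adjusted over all genes, 1 member was called in the LEA list and 0 in the others, but over the list alone 27 photosynthesis genes were called. With an estimated correlation these gave adjusted p = 0.611, 0.107, 0.123, 0.428, 0.736 and 0.237. Without Col-0 control replicate 2 the storage lists were no longer called, at 0.276 for ago4-2 and 0.34 for ago4-3. The ago4-2 lists for cell-wall loosening and osmotic stress ended at 0.0775 without Col-0 control replicate 1 and at 0.14 without Col-0 NaCl replicate 1, where the ago4-3 cell cycle list ended at 0.095.

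Outside the 17751 genes fitted, 300 genes lacking counts in some libraries were called in at least 1 comparison of the libraries that held them. Salt in Col-0 had 132 of 420, of which 39 were higher and 93 lower in NaCl.

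In ago4-2, 40 genes were near on or off against Col-0 in both conditions, 24 on and 16 off, by limits of 0.5 and 2 CPM. Of these, 12 lay on chromosome 2, 8 on chromosome 3 and 18 on chromosome 4. In all, 69 pairs lay 100 kb to 2 Mb apart, against a median of 26 and a highest of 57 in 10000 random sets. Segments of another genetic background in ago4-2 would give such clustering. Overlapping or adjacent genes, such as AT4G19239 and AT4G19240, repeat each other's pairs, and the random sets were matched on expression only. The excess is therefore probably overstated, by an amount that was not measured. Only 12.5% of the 40 genes (5 of 40, 95% interval 4.19 to 26.8) were called in the same direction in ago4-3 in both conditions. This argues against loss of AGO4 common to both alleles as the cause for most of the 40. Those 5 were all among the 24 on genes, and independent sets would share 0.0451 near on or off genes. For these 5, loss of AGO4 stays open. Transcripts shared with ago4-3 could come from ago4-3 material mixed into ago4-2, but the lowest such share, 13.2% for ESM1, is argued against by 9 genes, SADHU1-1 (131 CPM in ago4-3 and 0.200 in ago4-2 in control) among them, that lay under 0.5 CPM in ago4-2 where that share alone would give at least 2 CPM. A change particular to the ago4-2 allele, acting on clustered genes, was not tested. SUVH9, RPP4, CYP707A1 and LHCB5, named above, lie among these chromosome 4 genes, as do CRC, SESA1, SESA2, LDOX and XTH19. MCM5 (chromosome 2, start 3522984) and LHCA4 (chromosome 3, start 17493343) lie close to genes off in ago4-2. For all of these, background and allele cannot be told apart. Other named genes in such stretches may share this limit.

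Photosynthesis genes lay lower in the ago4-2 response to salt (median −1.45). That list call did not hold with an estimated correlation (camera adjusted p = 0.0751). The ago4-3 median lay in the same direction (−0.57), and the explanations below were weighed for ago4-2 only. Without the 10 most abundant genes of any library 38 of 41 were still lower, but TMM scaling already limits the weight of such genes, so this test could hardly decide. The median term over all genes was −0.0158, so photosynthesis genes lay lower relative to genes at large. This argues against a few abundant genes taking counts from the rest. A larger share of ungerminated seed in ago4-2 in both conditions cannot be told apart, since the photosynthesis median in control was 0.0894 (quartiles −0.1515 to 0.398) while all 16 storage genes (median 3.12) and 16 of 24 LEA genes were higher there. Slower germination in NaCl alone stays open as a biological explanation and was not tested. Another hour of harvest could also contribute, as 7 of 10 clock genes differed between ago4-2 and Col-0 in NaCl, where 29.34% of all genes were called. The predicted opposite move of morning and evening genes was not met in full. Of morning genes, LHY (0.81) and RVE8 (0.90) were higher but CCA1 (−1.86) lower. Of evening genes, GI (−3.83) and ELF4 (−0.56) were lower, and TOC1, PRR5 and PCL1 were not called. The hour and the genotype cannot be told apart here.

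Clock genes, chosen after their values were seen, changed with salt, 6 of 10 in the same direction in all 3 genotypes. LHY moved by −4.13 in Col-0, −3.42 in ago4-2 and −4.53 in ago4-3, and PRR5 by 1.11, 0.94 and 1.58. Control and NaCl libraries harvested at different hours might give this, as might an effect of salt on the clock, and the data cannot tell them apart because no harvest hour is given in the sources used here.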

How the results depend on the processing

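Calls were recounted under each alternative, in the order salt in Col-0, ago4-2 and ago4-3, ago4-2 and ago4-3 against Col-0 in control, the same in NaCl, ago4-3 against ago4-2 in control and NaCl, and the interactions of ago4-2 and ago4-3. With a fold of at least 2 also required, the first 10 counts were 653, 1373, 954, 447, 149, 1109, 137, 552, 781 and 253, because fewer genes can pass, and the last stayed at 4. With DESeq2, ago4-3 against Col-0 gave 465 in control and 348 in NaCl, and its interaction 54. Fitted on their own groups alone, ago4-2 and ago4-3 against Col-0 in control gave 887 and 624, ago4-3 against ago4-2 in control 650, and the ago4-3 interaction 9. With 1 library left out, in the same order, counts ranged from 1390 to 2441, 3916 to 5880, 2128 to 3113, 533 to 2420, 92 to 306, 2804 to 4223, 87 to 149, 879 to 1661, 1867 to 2286, 254 to 1129 and 1 to 19. Genes shared by both mutants, 81 in control, were 39 at p 0.01, 152 at 0.1, 35 with the fold, and 22 to 223 with 1 library left out. In NaCl, the 130 were 53, 204, 65, and 46 to 98. A replicate block by number gave 2881, 5923, 3755, 1220, 235, 4815, 187, 1440, 3354, 596 and 3, with 70 and 114 shared, all within 1.5 times. Residual correlations between equally numbered libraries ran from −0.411 to 0.251 over 15 pairs of groups, 2 of them over 0.1 and 5 under −0.1. With 2 libraries per group these neither show nor exclude that the numbers pair samples, and the labels do not say. The block called 1 list more, root genes in ago4-3 against Col-0 in NaCl (0.0382), and changed no other list call, and it ended 33 of 650 named-gene calls. Chosen after seeing the data, pairing by number within own groups gave 907 for ago4-3 against ago4-2 in control and crossed pairing 2040, and in NaCl 3808 and 6421. Without the 2213 genes of clustered 2 Mb windows, also chosen after, ago4-2 against Col-0 gave 978 in place of 1498 in control and 4283 in place of 5209 in NaCl. Without 18 abundant genes, counts were 6252, 1505, 5227, 808 and 4 for salt in ago4-2, ago4-2 against Col-0 in control and NaCl, and the interactions. Results that reversed were the organelle list without ago4-2 control replicate 2 (5.35e-05 for salt in ago4-2, 3.73e-05 between mutants in control and 5.6e-08 in the ago4-2 interaction), without ago4-2 control replicate 1 (0.00638 for ago4-2 against Col-0 in control, with the plastid gene ATCG01230 at −0.16) and without ago4-3 NaCl replicate 1 (0.00651 for ago4-3 against Col-0 in NaCl), and the storage list in the ago4-3 interaction without ago4-3 control replicate 2 (0.641). With 1 library left out these ranged, in that order, from 1.03e-15 to 0.28, 1.54e-33 to 0.0272, 4.31e-20 to 0.988, 2.75e-28 to 0.0315 (ATCG01230 to 3.56), 1.76e-07 to 0.492 and 2.08e-09 to 0.641. DESeq2 size factors moved no count beyond 1.5 times and kept 229 of 231 list results and 645 of 650 named genes, the DESeq2 test 635 of 645 named genes, and own groups 601 of 645. With an estimated correlation 146 lists were unchanged and 85 weaker, and with fry 181 were unchanged, 21 weaker and 29 stronger. Dropping the filter changed nothing, as it removed 0 genes. Except for the fold and the left-out libraries, the cause was not tested. Genes with few counts in the lower group have wide intervals at this depth.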

Other observations

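The near on or off genes, chosen after their values were seen, shared 5 members between the mutants. AT4G19240 had 0 counts in Col-0 and 116 ± 12.2 CPM in ago4-2 in control and 123 ± 3.85 in NaCl. AT2G11240 was off in ago4-2 and stood at 49.2 CPM in Col-0 in control. In ago4-3, 20 genes were near on or off, 19 on and 1 off, the off gene being the latex protein-like MLP31. Of those on, AT1G24851, AT1G25025, AT1G25112 and AT1G25180 start between 8778280 and 8829564 on chromosome 1, at 2.75 to 3.41 CPM in control. AT1G59920 and AT1G59930 are neighbours too. Reads may be shared within these sets, so the 19 may not be separate loci. AT1G59920 had 0 counts in Col-0 and ago4-2, and 2.31 and 7.97 CPM in ago4-3 in control and NaCl. The 5 genes on in both mutants were AT2G11410, AT2G21100, AT3G28290, AT4G01975 and AT5G35935. Of those on in ago4-3 alone, AT2G01422, AT4G08093 and AT3G28300 stood at 1.85, 1.82 and 1.69 CPM in ago4-2 in control. Pairs 100 kb to 2 Mb apart numbered 5 in ago4-3, against a median of 6 in random sets.

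The evening clock gene GI responded to salt in opposite ways. Its level went from 8.33 to 23.7 CPM in Col-0 (1.52) and from 10.3 to 29.4 CPM in ago4-3 (1.51), but from 5.35 to 1.67 CPM in ago4-2 (−1.67). In NaCl, ago4-2 lay below Col-0 in GI (−3.83, edgeR adjusted p = 3.8e-10), CCA1 (−1.86) and PRR7 (−1.75), and above it in RVE8 (0.90) and LHY (0.81). With salt, RVE8 fell in each genotype (−1.64, −1.35 and −1.56), and TOC1 (0.67, 0.52 and 0.91) and PCL1 (0.66, 0.72 and 0.72) rose. ELF4 rose in Col-0 (0.59) and ago4-3 (0.86) and was not called in ago4-2 (−0.29, adjusted p = 0.0944).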
